A study of Mus musculus with 3 samples.

How the data were processed

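DNA methylation was measured by methylated DNA immunoprecipitation followed by sequencing (MeDIP-seq), in which an antibody enriches fragments that carry methylated cytosines. Per the labels, there were 3 libraries of mouse CD8 T cell DNA: 1 from naive cells, 1 from effector cells taken 8 days after infection, and 1 input library. The cells were P14 cells, which carry a transgenic T cell receptor for an epitope of lymphocytic choriomeningitis virus (LCMV). Per the labels' protocols, 100000 congenically marked naive cells were transferred into each recipient, which was infected 24 hours later with 200000 plaque-forming units of the Armstrong strain, and both populations were sorted by flow cytometry. Libraries were made from 2 µg of DNA, size-selected at 200 to 400 bp before the immunoprecipitation and amplified for 15 cycles.

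The authors deposited 1 list of 646673 differentially methylated regions for the whole series. Its name gives a threshold of 1.5-fold. Each region has a position, a text label (D0 or D8) and a BED score, and the deposited score is 1 in all of them, so that it carries no measurement. The list holds no read count, signal, fold change or p-value per region. The submitters' processing notes name Bowtie, bedtools and the mm9 genome build, without versions, role or order. How windows were counted and normalized, which test was applied, and how the input was used are not given in the sources used here. The depth of the libraries is unknown, so no limit of detection can be given. All 646673 starts lie 1 past a multiple of 100 and 646671 of the ends lie on a multiple of 100, so positions were read as 1-based and inclusive windows on a 100 bp grid. On chromosome 1 the list runs to position 197194400, beyond the last gene of the GRCm38 annotation table used here, and positions are given in mm9 throughout.

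The list does not say what the label means. D8 is in the title of the day 8 effector library, and D0 was taken as the naive library. Whether a label marks the library with the higher or the lower methylation is not stated and could not be settled from the values, so all results are given by label and no gain or loss of methylation is claimed.

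Each group had 1 library, so there is no replicate error and no test between the conditions. Intervals on shares are exact Clopper-Pearson 95% intervals. They cover counting error only and treat regions as independent, which neighbouring regions are not. The design fixed before the data were examined asked for the count per label, the distribution over chromosomes and the clustering of regions. For clustering, regions of 1 label were merged into blocks where the gap between them was at most 1 kb. Regions of the other label were ignored in this merging, so a block may enclose some of them. The share of neighbouring regions with the same label was set against 1000 shuffles of the labels within each chromosome. Windows of 1 Mb, with at least 20 regions each, runs of consecutive regions with 1 label, and regions within 100 bp of each other were examined after the data had been seen. Correlations across chromosomes were tested by permutation (100000 resamples, two-sided). The statistics were tested on simulated data: on the 646092 regions of the 20 chromosomes with labels drawn at random, the share of same-label neighbours differed from its shuffled mean by 0.030 percentage points, and 24 of 25 planted stretches, each of 100 regions with a 95% chance of the D8 label, gave a run longer than any in 20 shuffles, with 0 such runs elsewhere. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used.

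The rule for named items was fixed before the data were examined. It asked for genes of 17 preset lists with a region at their promoter, the promoters with the largest fold, and the 5 longest blocks per label. Only the blocks could be named. The list of regions gives no gene names, and the annotation table is of GRCm38, so no mm9 annotation was used here and regions were not assigned to genes, promoters or exons. The 17 preset gene lists (T cell effector, naive and memory genes, markers of other cell types and unrelated controls among them) and the promoter comparison were therefore not analysed. The size of the difference per region was not analysed, because no fold is given. From the annotation table only the number of protein-coding genes per chromosome was taken.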

Results

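The series asked how DNA methylation differs between naive CD8 T cells and the effector cells they give rise to by day 8 of an acute viral infection. MeDIP-seq was run on 1 library of naive and 1 library of day 8 effector cells specific for LCMV, with 1 input library. The values behind the regions, and the depth of the libraries, are unknown, and what follows describes the positions and labels of the 646673 regions that the authors called different at 1.5-fold.

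Differences between the naive and the effector library were listed on all autosomes and on chromosome X, and both labels were common. Regions labelled D8 numbered 350666 and regions labelled D0 numbered 296007, a ratio of 1.18. D8 regions were thus 54.2% of the list (95% interval 54.1% to 54.3%, counting error only). Because the list does not state whether D8 marks more or less methylation in effector cells, the direction of this imbalance is left open. D0 regions covered 81.7 Mb and D8 regions 99.7 Mb of the mm9 genome, leaving out 21 regions that are longer than 2 kb and span a power of 10 in their coordinates.

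Most regions were short, close to the size of the sequenced fragments. The median length was 300 bp for both labels, with quartiles of 200 and 300 bp. The shortest common class, 200 bp, held 48.3% of D0 regions and 47.4% of D8 regions. Long regions were more often labelled D8. Regions of 500 bp or more made up 6.94% of D8 regions (interval 6.85% to 7.02%) and 4.86% of D0 regions (interval 4.78% to 4.93%), a ratio of 1.43. Without the same 21 regions, 479 D8 regions and 175 D0 regions reached 1000 bp, and the share of such regions was 2.31 times as high for D8. If touching windows of 1 label were joined when the list was made, the larger number of D8 regions could give part of this contrast in length. That was not tested, since the list holds no windows before joining. With 1 library per cell type, none of these differences has a replicate check.

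The D8 label was in the majority on each of the 19 autosomes and on chromosome X, but to a different extent. The highest D8 shares were on chromosome 11 (57.0%, interval 56.5% to 57.5%), chromosome 17 (56.9%, interval 56.3% to 57.5%) and chromosome 4 (56.7%, interval 56.2% to 57.2%). The lowest among autosomes were on chromosome 9 (51.9%, interval 51.3% to 52.4%) and chromosome 3 (52.0%, interval 51.5% to 52.5%). These intervals do not overlap, so the spread between chromosomes exceeds counting error under independence. Chromosome 11 carried 135 D0 and 179 D8 regions per Mb, and chromosome 9 carried 143 D0 and 154 D8 regions per Mb. These were the highest D0 densities of the 20 chromosomes, so both labels were dense on each of them.

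Chromosome X stood apart in density. It carried 103 regions per Mb, against 254 per Mb over the autosomes and at least 216 per Mb on any single autosome, so that autosomes were 2.47 times as dense. Both labels were sparse there, with 50.3 D0 and 52.8 D8 regions per Mb. Read depth on X is unknown, so the lower density cannot be read as fewer methylation differences there. The D8 share on X was 51.2% (interval 50.4% to 51.9%) and that of the autosomes 54.3% (interval 54.2% to 54.4%), a difference of -3.10 percentage points (X minus autosomes). Chromosome Y had 0 listed regions. No floor can be attached to that count, because it is not known whether reads on Y were kept.

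**Figure D1:**
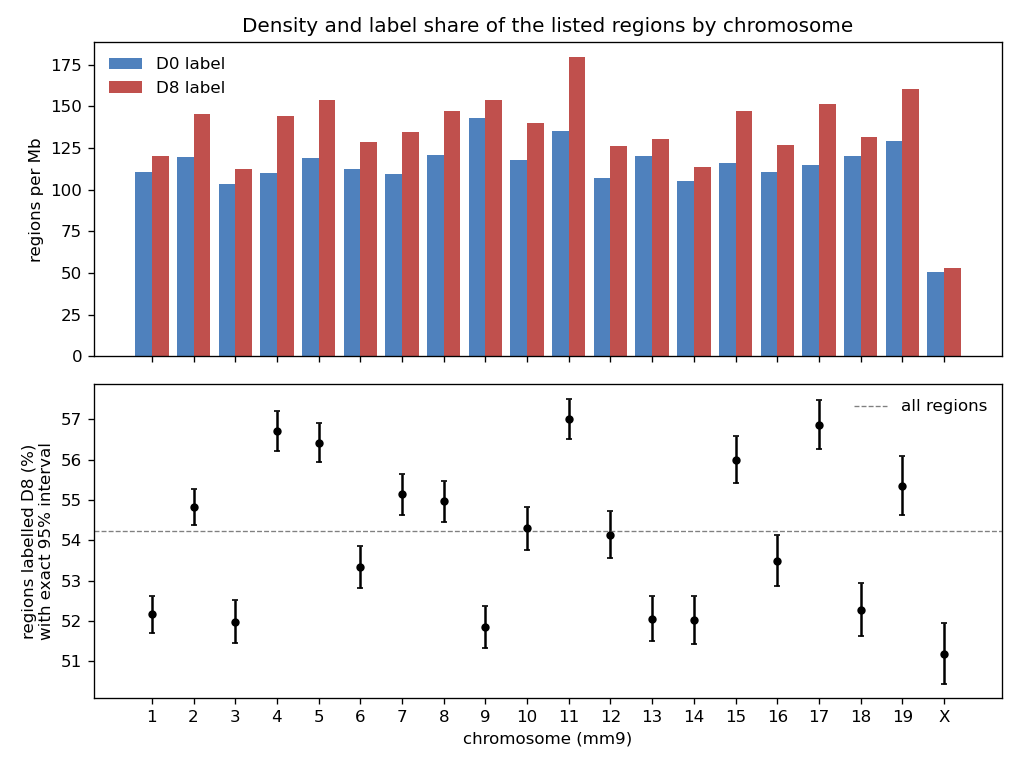
Upper panel: listed regions per Mb (vertical axis) on each mm9 chromosome, with D0 in blue and D8 in red; lower panel: the share of regions labelled D8 in percent, with exact 95% intervals for counting error, and a dashed line at 54.2% for all regions. Chromosome X has the lowest density of both labels, and D8 shares range from 51.2% on X to 57.0% on chromosome 11.

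Within chromosomes, the label share varied from one megabase to the next by more than random placement gives. Over 2531 windows of 1 Mb with at least 20 regions, the variance of the D8 count around its chromosome's mean share was 5.28 times the binomial value. In 1000 shuffles of the labels within chromosomes this ratio averaged 0.994 and never exceeded 1.07. D8 shares of 65% or more were found in 145 windows, against a mean of 22.7 and a maximum of 37 in the shuffles. Shares of 40% or less were found in 49 windows, against a mean of 9.61 and a maximum of 20.

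The windows with the highest D8 share lay on chromosome 14 at 54 to 55 Mb (122 of 142 regions, 85.9%, interval 79.1% to 91.2%) and on chromosome 4 at 146 to 147 Mb (42 of 50 regions, 84.0%, interval 70.9% to 92.8%). Next came chromosome 17 at 22 to 23 Mb, with 73.1% of 67 regions. Windows with many regions followed, among them chromosome 2 at 165 to 166 Mb (368 of 505 regions, 72.9%), chromosome 7 at 52 to 53 Mb (72.2% of 493) and chromosome 5 at 115 to 116 Mb (71.8% of 489). The lowest D8 share was on chromosome 9 at 59 to 60 Mb, where 111 of 363 regions carried the label (30.6%, interval 25.9% to 35.6%). Another window of chromosome 9, at 41 to 42 Mb, had 167 of 501 regions labelled D8 (33.3%, interval 29.2% to 37.7%). These windows were picked as extremes after their values were seen.

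The D8 share also went with how many regions a window held. The windows were split into 5 groups of similar size by their number of regions. In the sparsest group (20 to 104 regions per window) the D8 share was 52.0%, and in the next 2 groups it was 49.1% and 49.9%. It was 53.6% in the group with 307 to 395 regions and 59.1% (interval 58.9% to 59.3%) in the densest (396 to 627 regions). Within single chromosomes, Spearman's rho across windows between density and D8 share was positive on 19 of the 20 chromosomes, up to 0.66 on chromosome 11. It was -0.30 on X. Windows of a chromosome are not independent replicates, so no p-value is attached.

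Neighbouring regions shared their label slightly more often than in the shuffles. Of 646072 pairs of consecutive regions, 51.7% had the same label, against a mean of 50.4% and a range of 50.2% to 50.6% in the shuffles, an excess of 1.30 percentage points. Touching pairs in the list all have opposite labels, which shuffling does not keep. Without touching or overlapping pairs, an alternative added after the data were seen, 52.5% of 636020 pairs had the same label, against a mean of 50.4% and a range of 50.2% to 50.6% in the shuffles, an excess of 2.12 percentage points. The excess faded with distance. The same-label share was 57.2% (interval 56.6% to 57.8%) for gaps of 201 to 300 bp, 54.9% for gaps of 501 to 1000 bp and 53.2% for gaps of 1001 to 2000 bp. For gaps of 16001 to 32000 bp it was 50.7% (interval 49.96% to 51.5%), an interval that includes the shuffled mean. Shuffles within windows were not run by gap. Part of the fall may therefore reflect the higher D8 share of the densest windows, where regions lie closest together.

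For gaps of up to 100 bp opposite labels were in the majority. Among 30532 pairs with a gap of 1 to 100 bp, only 39.3% (interval 38.7% to 39.8%) had the same label. A further 10027 pairs touched and had opposite labels. Touching pairs of the same label number 0, which carries no information if touching windows of 1 label were joined when the list was made. Such joining would also remove same-label pairs with a short gap wherever the windows between them were called, but no opposite pairs. The low share at gaps of 1 to 100 bp therefore cannot be read apart from how the list was made. In all, 55503 regions, 8.59% of those on the 20 chromosomes, lay within 100 bp of a region of the opposite label.

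**Figure D2:**
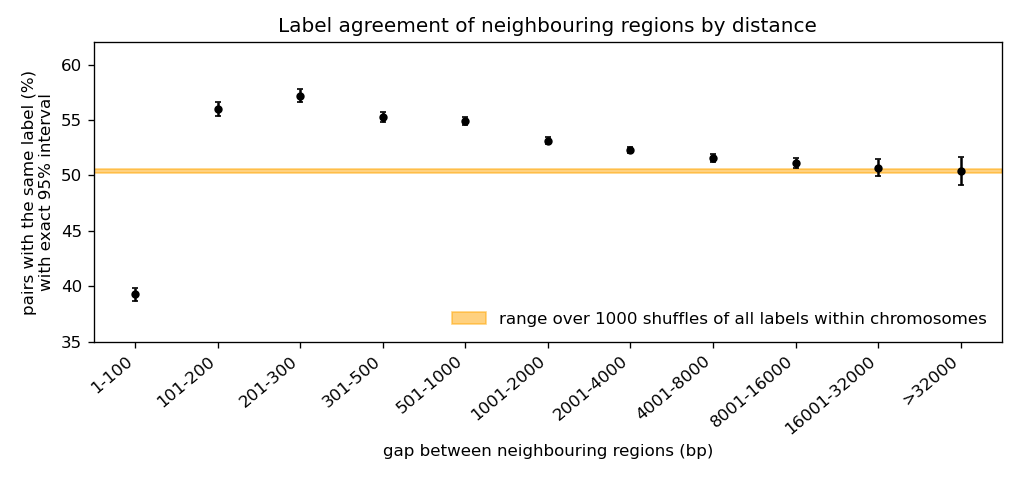
Share of neighbouring regions with the same label in percent (vertical axis) by the gap between them in bp (horizontal axis), with exact 95% intervals for counting error; the orange band is the range over 1000 shuffles. Touching regions are left out; agreement is 39.3% for gaps of 1 to 100 bp, is highest at 57.2% for gaps of 201 to 300 bp and declines to the band at long distances.

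Regions joined into blocks more often under the D8 label. After merging regions of 1 label with gaps of at most 1 kb, there were 271043 D8 blocks and 247434 D0 blocks, of which 78.7% and 84.1% held a single region. Blocks of 3 or more regions held 14.9% of D8 regions (15158 blocks) and 8.05% of D0 regions (7327 blocks). Blocks of 10 or more regions numbered 17 for D8 and 0 for D0, whose fullest block held 9. Part of this contrast follows from the larger number of D8 regions. In 100 shuffles of the labels within each chromosome or contig, added after the data were seen, blocks of 3 or more held 11.9% to 12.3% of D8 regions and 8.86% to 9.18% of D0 regions. Blocks of 10 or more numbered at most 5 for D8 and 2 for D0. The listed D8 regions were thus above and the D0 regions below the shuffled range in their share within blocks of 3 or more. Shuffling can give touching regions the same label, which the list does not hold. It also does not keep the higher D8 share of the densest 1 Mb windows, where regions lie closest together. Shuffles within windows were not run for blocks, so the contrast between the labels cannot be told apart from that relation.

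The longest blocks by the fixed rule were largely those that contain a region spanning a power of 10 in its coordinates: all 5 D8 blocks and 3 of the 5 D0 blocks. The longest was 677 kb for D8, in the set of contigs assigned to chromosome X, and 23.1 kb for D0. Leaving such blocks out, which was decided after seeing the data, the longest D8 block was on chromosome 3 from 130861701 to 130884100 (22.4 kb, 21 regions). It was followed by chromosome 12 from 109179801 to 109197100 (17.3 kb, 13 regions) and chromosome X from 166407001 to 166423800 (16.8 kb, 16 regions). The other D8 blocks were both on chromosome 5 and both 10.4 kb long, with 12 regions from 130763401 and 11 regions from 142893701. The longest D0 blocks were shorter: chromosome 9 from 47710801 to 47717600 (6.8 kb, 6 regions), chromosome 15 from 61973201 to 61979800 (6.6 kb, 7 regions), and chromosomes 10 and 16 with 6.3 kb each, from 85844201 and 59553801. The remaining one was on chromosome 12 from 92154701 (6.2 kb, 9 regions).

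Uninterrupted runs of 20 or more consecutive regions with 1 label were nearly all labelled D8. There were 56 runs of at least 20 D8 regions, against a mean of 1.72 and a maximum of 8 in the shuffles within chromosomes. Shuffles within 10 Mb windows gave a mean of 4.68 and a maximum of 13. When regions of 1 label within 1 kb were merged first, 5 such runs were left. Labels of merged blocks were not shuffled, so this count cannot be set against the shuffled counts. Without merging, D0 had 1 run of at least 20 regions, on chromosome 3 from 131421701 to 131499900. The shuffles within chromosomes gave a mean of 0.086 and a maximum of 2 for D0. The longest D8 run held 97 regions on chromosome 3, from 130796701 to 130932200 (136 kb), and contained the longest D8 block. It was flanked by sequence with both labels, where 48.7% of the 711 regions in the 1 Mb on either side were labelled D8. The next held 82 regions on chromosome 14 from 53731101 to 54768600 (1038 kb), 49 regions on chromosome 19 from 37323201 to 37404000 (80.8 kb) and 48 regions on chromosome 6 from 41047201 to 41512700 (466 kb). The run on chromosome 14 overlaps the 1 Mb window with the highest D8 share, at 54 to 55 Mb, so these are not separate results.

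A total of 9 runs, all labelled D8 and holding 458 regions, were longer than the longest run in the shuffles within chromosomes (32 regions). The 6 longest, with 353 regions, were also longer than the longest run in the shuffles within 10 Mb windows (37 regions). Besides the 4 above, the 9 runs lay on chromosome 11 from 3000301 to 3098100 (39 regions), chromosome X from 166308201 to 166585100 (38 regions), chromosome 11 from 52012001 to 52099500 (36 regions), chromosome 18 from 75515901 to 75581700 (36 regions) and chromosome 6 from 83297801 to 83367300 (33 regions). The density of regions differed widely between them. It was 716 regions per Mb in the run on chromosome 3 and 606 in that on chromosome 19, which is 2.01 and 1.62 times their flanks. It was 79.0 per Mb on chromosome 14 and 103 per Mb in the 48-region run on chromosome 6, which is 0.30 and 0.55 times their flanks. Runs were examined after the data had been seen, and the genes they contain were not looked up because no mm9 annotation was used here.

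**Figure D3:**
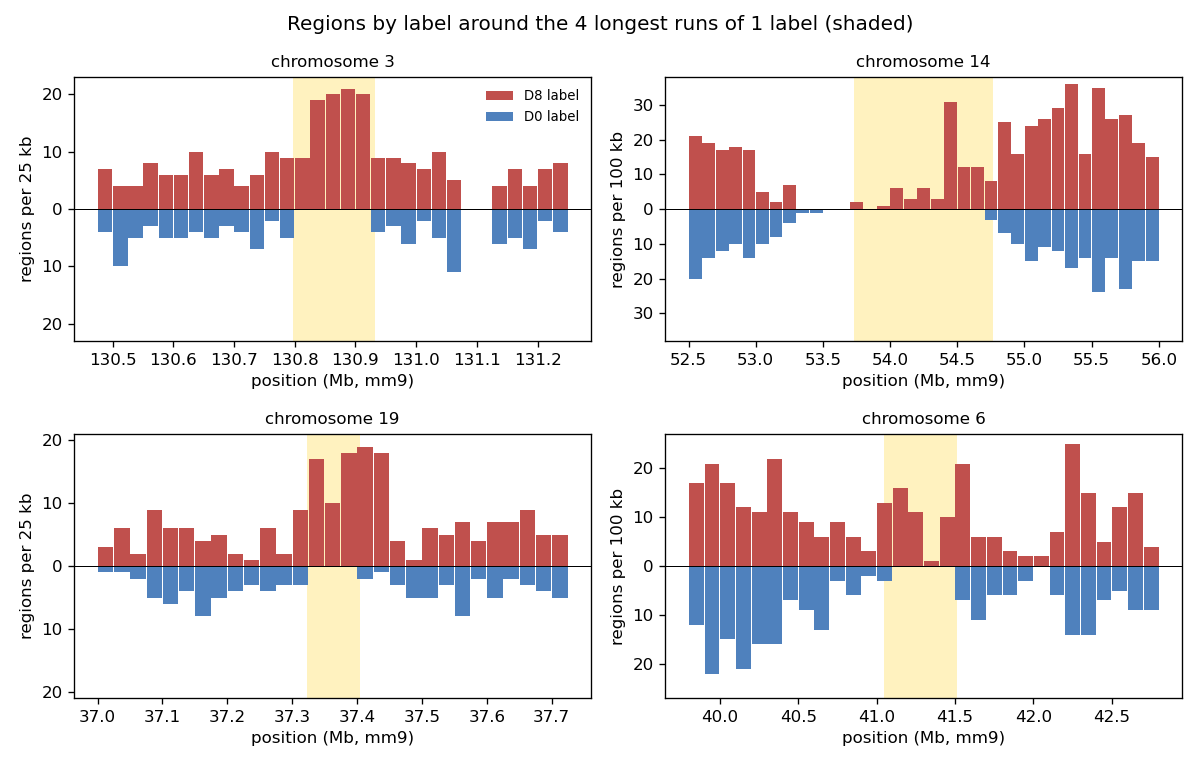
Number of listed regions in 25 kb windows (chromosomes 3 and 19) or 100 kb windows (chromosomes 14 and 6) along mm9 positions in Mb, with D8 above the zero line in red and D0 below it in blue; the shaded stretch is the run. Both labels are present on either side of each run, and the run on chromosome 3 holds 97 D8 regions and 0 D0 regions.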

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

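Of the tests in this part, those on powers of 10 and on runs were chosen after the results were seen; those on pairs of opposite labels were set before their results were computed.

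Regions were also listed outside the 20 assembled chromosomes, on sequence that entered the total counts, lengths and blocks above but not the comparisons of chromosomes, windows, neighbours and runs. The unplaced set of contigs (Un_random) carried 337 regions, and 258 of them were labelled D8 (76.6%, interval 71.7% to 80.98%). The 6 sets of contigs assigned to a chromosome carried 242 regions, 54.5% of them labelled D8 (interval 48.0% to 60.9%). The mitochondrial genome carried 2 regions, both labelled D8, which is not above that limit.

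The list contains 24 regions longer than 2 kb, up to 676 kb, and 21 of them span a position that is a power of 10, such as 10 or 100 Mb on an assembled chromosome. A candidate cause is that positions were compared as text while windows of 1 label were merged, since a number with one more digit then sorts before its predecessor. The data fit this in detail: no region spans the power of 10 at 26 of 50 such positions, and at 26 of those 26 the nearest regions on the sides carry opposite labels, where windows of 1 label would not meet. Broad domains that differ between the cell types have no reason to sit there, and the share of 87.5% of long regions on a power of 10 argues against them. The 3 other long regions reach at most 2.5 kb, so the lengths of the 21 regions are better not read as measured extents.

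Opposite labels within 100 bp of each other were the next pattern. A shift of all reads of one library in 1 direction would put the same label on the left each time. D0 was on the left in 49.9% of 10027 touching pairs (interval 49.0% to 50.9%), which argues against such a shift. A difference that moves reads of opposite strands in opposite directions would not change this share and was not tested. Broader enrichment peaks in one library would favour one order of alternating triplets. The D8, D0, D8 order occurred 966 times and the D0, D8, D0 order 671 times, 1.22 times the ratio that the label shares give (interval 1.10 to 1.34). That is an excess over the label shares of all regions, but below the 1.5 set beforehand for breadth as the main cause. With random labels, the D8, D0, D8 order would have the same share of triplets as D8 has of regions. It held 59.0% of the triplets, and the D8 share in the densest group of 1 Mb windows was 59.1%. The excess may therefore reflect triplets that lie in dense windows. Where they lie was not examined. Joining of windows of 1 label when the list was made, sampling of few reads per window and switches of methylation over short distances remain open. They were not tested, since the list holds no windows before joining and no read counts.

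The long D8 runs were the last pattern. The shuffles argue against chance order: the longest run among 1000 shuffles within chromosomes held 32 regions, and a slow drift of label shares, imitated by shuffles within 10 Mb windows, gave at most 37, against 97 observed. Only the 6 longest runs exceed 37, so for the other 3 runs, with 33 to 36 regions, drift stays open. A difference in DNA copy number between the cell preparations may also give stretches of 1 label with sharp edges, and cannot be told apart from methylation here, because neither a signal nor an input value per region is in the list. T cell receptor genes lose DNA when they rearrange in T cells, and whether any run covers such a gene was not determined. Both libraries came from CD8 T cells, so such a loss may be present in both and need not give 1 label. Of the 9 runs beyond the shuffles within chromosomes, 6 were counted as denser in regions than their flanks and 3 as sparser, among them those on chromosomes 14 and 6 with 82 and 48 regions. Flanks were counted over 1 Mb on each side. The runs on chromosome 11 from 3000301 and on X had listed regions on 1 side only. Against that 1 Mb, the chromosome 11 run was not denser, with 399 regions per Mb against 410 in the flank. The X run stayed denser, with 137 per Mb against 104. Sparser runs are not excluded by their lower density, since density also depends on how many CpG sites and mappable windows a stretch holds. A domain that changed methylation between naive and effector cells stays open, as untested, for these runs.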

How the results depend on the processing

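Of the 16 alternatives, 7 left the value within its counting error or, for counts, within 1.5 times. The alternatives without regions spanning a power of 10, and all those for same-label neighbours and for runs, were added after the data were seen. The D8 share of 54.2% was 52.3% when regions of 1 label within 1 kb were merged, 55.3% by base pairs covered and 54.95% by base pairs without the regions spanning a power of 10; D8 stayed in the majority in each. The number of blocks of 3 or more regions, 22485 at a merging distance of 1 kb, was 77467 at 5 kb, so it depends strongly on the distance. At 0 bp it was 0, which carries no information if touching windows of 1 label were joined when the list was made. The excess of same-label neighbours, 1.30 percentage points, was 2.12 without touching or overlapping pairs, 1.75 for pairs more than 1 kb apart, and 0.97 when labels were shuffled within 10 Mb windows, so that part of it reflects label shares that vary along chromosomes. The 56 runs of 20 or more D8 regions became 5 when regions within 1 kb were merged first. Such merging shortens a run wherever its regions lie within 1 kb of each other. The longest run then held 66 blocks. No paired analysis was possible because each group has 1 library, and no replicate could be left out. Alternatives with a 2-fold or 3-fold threshold, a signal minimum, a pseudocount or centring, and those for promoters and gene lists, were not run because the list holds no values per region and no gene names. Depth is unknown, so an absence of regions at a locus cannot be read as an absence of difference.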

Other observations

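The tests in this part were chosen after the chromosome shares were seen. The D8 share was higher on chromosomes with more protein-coding genes per Mb, counted from a GRCm38 gene table. The length used, as for regions per Mb, was the end position of the last listed region in mm9. Across the 20 chromosomes Pearson's r was 0.64 (permutation p = 0.0029, adjusted 0.0058 over 6 relations) and Spearman's rho was 0.66 (permutation p = 0.0017, adjusted 0.0034). Without chromosomes 7 and 11, the farthest from the median gene density, r was 0.60. Across the 19 autosomes alone r was 0.61 (permutation p = 0.0063, adjusted 0.0095). Chromosomes are not independent samples of the cells, and these values describe 1 pair of libraries.

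The density of D8 regions was higher on gene-rich chromosomes. Over the 19 autosomes, Spearman's rho with genes per Mb was 0.77 for D8 regions per Mb (permutation p = 0.00016, adjusted 0.00048) and 0.42 for D0 regions per Mb (permutation p = 0.075, adjusted 0.075). Pearson's r for D0 was 0.48 (permutation p = 0.0488, adjusted 0.0488) and for D8 it was 0.72 (permutation p = 0.00038, adjusted 0.0011), so the D0 relation lies close to the threshold and passes it by r but not by rho. With X included, rho for D0 was 0.48 (permutation p = 0.034, adjusted 0.041). The difference between the labels was not itself tested. Gene content, GC content and CpG density vary together between chromosomes, and no GC or CpG values of mm9 were used here, so the relation was not taken further.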
